A study of Homo sapiens with 4 samples.

How the data were processed

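Each of the 4 samples was 1 library of total RNA prepared with a stranded mRNA kit and a limited number of PCR cycles, per the labels' protocols. The labels name the line (A549 or H1993) and the culture (adherent or spheroid) of each library, and these labels gave the groups. Per the submitters' processing notes the genome build was hg38. The aligner, the counting program and the annotation release are not given in the sources used here.

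The authors deposited 1 table per library with 43622 genes. Per the file headers, each table holds whole-number counts of reads per gene (total and unique reads over genes, exons, introns and exon-exon junctions). Exon and intron counts summed to the gene count in every row. The deposited TPM (transcript abundance scaled by exon length) summed to 1e+06 in each library. The deposited RPKM (reads scaled by exon length and library size) was equal to the column named expression value in every row. The analysis below rests on the total exon counts, and TPM and RPKM entered no comparison. Gene positions are those of the files. Of the gene IDs, 43393 were in GENCODE release 29, and 97.0% of these had the same start and end there. Symbols are those of the files, with the current symbol where it differs. It is not stated whether counting used strand, so antisense and overlapping genes are uncertain, and genes with closely similar copies (PSG5, ANXA8 and ANXA8L1, AKR1C genes, HSPA1A and HSPA1B) may share reads.

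Total exon reads were between 15331121 and 17681746 per library, so 3 reads correspond to between 0.170 and 0.196 CPM. Intronic reads made up 10.1% of gene reads in A549 adherent cells, 8.43% in A549 spheroids, 10.7% in the library labelled H1993 adherent and 11.6% in H1993 spheroids. Mitochondrial genes took 6.59%, 6.68%, 8.29% and 4.57% of exonic reads in that order. PCR duplicates cannot be told from separate molecules here, so all intervals and floors cover counting error only.

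Genes were kept by edgeR's filterByExpr (15273 genes) and scaled by TMM factors. Log2 folds used a prior count of 2 and the 95% interval of a fold was the exact Clopper-Pearson interval of the 2 counts. A kept gene was counted as higher or lower when its fold was at least 2 and its interval excluded no change. Genes not kept, among them some measured list members, were counted as neither, whatever their fold. This compares 2 libraries, not 2 conditions. Overlaps between lines were set against the product of the list sizes over the genes considered. A gene with 0 reads in 1 library was given a bound against a floor of 3 reads in that library. Folds with 1 to 3 reads in a library are given with their interval.

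A set of 39 gene lists was written before the data were examined. Members with at least 10 reads in 1 library of the line were measured, and the median log2 fold was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. A median outside the central 95% of these lists is said to stand apart, as a description of these libraries. 3 histone genes were not found under any symbol. In 7 of the list medians, a member had 0 reads in 1 library. With these members at their bound 2 medians moved, interferon response in H1993 from -2.31 to -1.97 and blood cell markers in H1993 from 1.94 to 1.58.

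Over both lines, edgeR's glmQLFit and glmQLFTest were run with culture and line as terms, which leaves 1 residual degree of freedom. DESeq2 with the same terms was the alternative tool. Genes were named by a rule written before the data were examined. It took the 12 highest and 12 lowest in both lines by the smaller of the 2 folds (at least 100 reads in the higher library of each line), the 5 highest and 5 lowest in each line (at least 500 reads), the 5 most opposite each way, a fixed set of lipid, YAP, TEAD, stem cell and antioxidant genes, and up to 4 members of each list. Some genes that the rule names are not reported here. Alternatives were other scalings, filters and prior counts, the other tool, no block for line, the mean in place of the median and protein-coding random lists. Unique exon reads, a fit without mitochondrial genes and A549 libraries alone were added after seeing the data.

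The libraries were compared with each other on autosomal genes by correlation across genes and by the median ratio in windows of 50 genes in chromosome order (9184 genes with at least 100 reads in each library, 173 windows). The position excess is the SD of the window medians divided by its mean over 1000 shuffles of gene order. A check for mixed-up samples found that 1 library did not match its group's labels. Y-linked genes and XIST were left out of the gene values given.

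The test over both lines, the 2-fold limit of the size rule, the random lists and the position excess were tested on simulated data. With 15273 simulated genes over both lines at a dispersion of 0.02, edgeR recovered 88% of genes changed 2-fold and 100% of those changed 4-fold. At 0.1 it recovered 3% and 59%, and at the fitted 0.233 it recovered 0% of each, where DESeq2 recovered 1% and 28% with 11 false calls. By the fold alone, without the counting interval, 1.31% of unchanged genes passed 2-fold in A549 at a dispersion of 0.02, and 32.7% did so at 0.233. Of 200 random lists per line 3.5% in A549 and 6.5% in H1993 lay outside the limits, and after a shift of 1 on the log2 scale 98.5% and 92.0% lay above them. The position excess was 1.01 with no planted effect and 2.35 with one. Software was R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.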

Results

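Messenger RNA was sequenced in 4 libraries from 2 human lung adenocarcinoma cell lines, A549 and NCI-H1993 (H1993). Each line was grown adherent, as a layer attached to plastic, and as spheroids, which are free-floating cell clusters used to enrich cells with stem cell properties. There was 1 library for each line and culture, so no difference between a pair of libraries has a replicate check. The study's stated purpose was to compare the triacylglycerol synthesis pathway between the 2 cultures, and its title links that pathway to the transcriptional coactivator YAP, to its TEAD partners and to resistance to reactive oxygen species. The libraries held 15657295 exonic reads in A549 adherent cells, 17681746 in A549 spheroids, 16606939 in the library labelled H1993 adherent and 15331121 in H1993 spheroids. Values below are log2 folds of spheroid over adherent with 95% counting intervals in brackets, and these intervals cover counting error only.

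The library labelled H1993 adherent was closer to A549 adherent cells than to H1993 spheroids. Over 14759 genes its log2 levels had a Pearson correlation across genes of 0.947 with A549 adherent cells and of 0.845 with H1993 spheroids, where genes are not independent replicates. Of these genes, 13.2% differed by at least 2-fold from A549 adherent cells and 35.6% from H1993 spheroids. For scale, A549 adherent cells and A549 spheroids had a correlation of 0.897, with 23.7% of genes at least 2-fold apart. CDKN2A and CDKN2B, neighbouring tumour suppressor genes, had 0 reads in both A549 libraries, but 75 and 89 reads in the library labelled H1993 adherent and 308 and 371 in H1993 spheroids. HNF4A, a hepatocyte and gut transcription factor, stood at 29.9 CPM (read counts scaled by library size) in A549 adherent cells, 0.058 CPM in the library labelled H1993 adherent and 0.33 CPM in H1993 spheroids. These 3 genes were chosen after their values were seen and lie at the extremes of their sets. CDKN2A and CDKN2B, at 21.5% and 21.2% of the H1993 spheroid level, were the highest of 43 genes on in H1993 spheroids and off in A549 (median 3.19%). HNF4A, at 0.19% of the A549 adherent level, was near the lowest of 14 genes on in A549 and off in H1993 spheroids. The median of that set was 13.7% and its highest value 94.2%. Along the autosomes, 25 of 173 windows of 50 genes had a median log2 ratio of at least 0.5 in size between H1993 spheroids and the library labelled H1993 adherent, against 0 windows in the A549 pair. Between the library labelled H1993 adherent and A549 adherent cells the count was also 0, and the lowest window lay at -0.49 on chromosome 9 (94726701 to 111654351, hg38). A count at 0.5 leaves out smaller shifts shared by neighbouring windows. On chromosome 9 the windows from 71683366 onwards lay at -0.28, -0.49, -0.37, -0.47 and -0.47, and between -0.19 and 0.02 in the A549 pair. On chromosome 15 those from 50424380 onwards lay at -0.40, -0.31, -0.15 and -0.25. The highest window of the adherent libraries lay at 0.26, on chromosome 5. Between H1993 spheroids and A549 adherent cells, which differ in line and in culture, 36 windows reached 0.5 in size. Across the 173 windows these ratios had a Pearson correlation of 0.93 with those of the H1993 pair, and both hold the H1993 spheroid library. An H1993 fold may therefore hold a difference between lines as well as one between cultures. Every H1993 fold below is given as the value of the libraries as labelled.

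**Figure D1:**
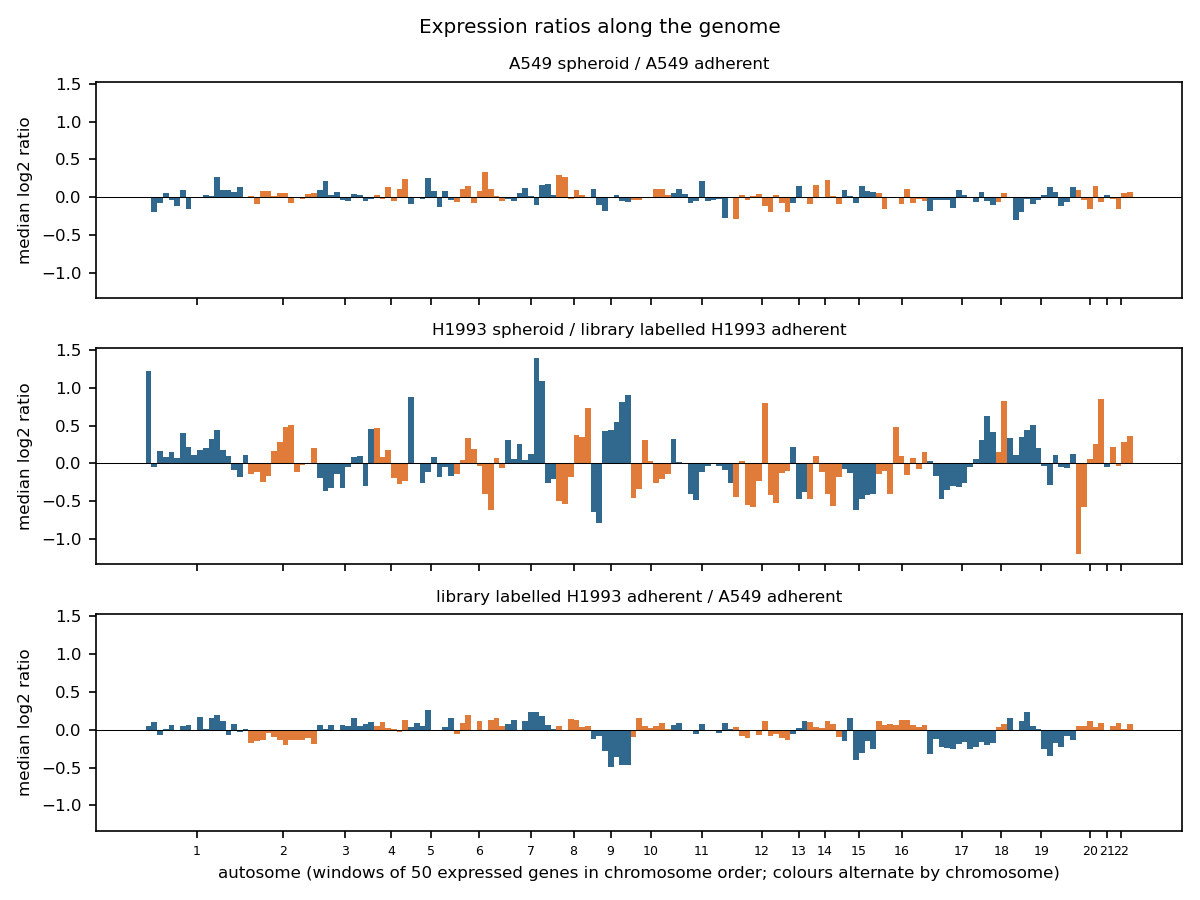
Median log2 expression ratio (y axis) in windows of 50 expressed genes in chromosome order (x axis, autosomes 1 to 22) for 3 pairs of libraries, 1 library each. The A549 pair and the pair of adherent libraries have 0 windows of at least 0.5 in size, and the H1993 pair as labelled has 25 of 173. In the pair of adherent libraries, neighbouring windows of chromosome 9 reach -0.49, -0.37, -0.47 and -0.47.

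In A549 cells, genes of cell division were far lower in spheroids than in adherent culture. MKI67, the proliferation marker Ki-67 (ENSG00000148773, chromosome 10, 128096659 to 128126385), had 6509 reads in adherent cells and 63 in spheroids, a log2 fold of -6.71 (-7.14 to -6.40). All 23 measured mitosis genes were at least 2-fold lower, with a median of -4.90, among them AURKB, a mitotic kinase, at -6.27 and CDC20, an activator of the anaphase-promoting complex, at -6.13. All 24 measured genes of S phase and replication were also at least 2-fold lower, with a median of -3.20. CDC45 and MCM5, parts of the replicative helicase, stood at -5.56 and -5.15, and RRM2, a subunit of ribonucleotide reductase, at -5.10. DIAPH3, MYBL2 and MCM10 completed the 5 lowest abundant genes, each at -6.51. The 5 highest were C2CD4A at 8.20 (1 read in adherent cells, interval 7.27 to 15.06), SLC14A1, a urea transporter, at 7.49 (also 1 read, 6.56 to 14.35), KRT20, an intestinal keratin, at 7.33 (6.70 to 8.65), FCGBP, a mucus protein, at 6.83 (6.71 to 6.97) and SCG2, a granule protein of neuroendocrine cells, at 6.62 (6.28 to 7.08).

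By the rule of at least 2-fold with a counting interval that excludes no change, 1888 of 15273 genes were higher and 1579 lower in A549 spheroids. With scaling by library size alone the counts were 1613 and 1827, and the median of all genes moved from 0.00 to -0.11 on the log2 scale. On simulated counts with no change, 1.31% of genes were at least 2-fold apart at a dispersion of 0.02 and 32.7% at 0.233. These shares rest on the fold alone, without the counting interval, so they are not shares under the full rule. By the fold alone, 23.7% of 14759 autosomal genes were at least 2-fold apart in the A549 pair, under the share at 0.233. The dispersion of 0.233 was fitted over both lines, so it also holds their differences in response. The spread between libraries of 1 line and culture is not known, so this comparison cannot decide either way. The counts alone do not show a culture effect by their size.

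The lipid droplet and triacylglycerol synthesis lists of A549 lay above most random lists. PLIN2, the coat protein of lipid droplets (ENSG00000147872, chromosome 9, 19108375 to 19149290), had 583 reads in adherent cells and 11878 in spheroids, a log2 fold of 4.28 (4.16 to 4.41). Of 15 measured lipid droplet genes, 8 were at least 2-fold higher and 0 lower, with a median of 1.68, above the 10000 random lists matched on expression (percentile 100). PLIN1, another droplet coat protein, stood at 4.43 (3.63 to 6.52), CIDEC, which fuses droplets, at 3.43 (3.02 to 4.02) and HILPDA, an inhibitor of droplet lipolysis, at 2.76. Triacylglycerol synthesis genes moved less. Their median was 0.42 (percentile 99.3), with 3 of 21 at least 2-fold higher and 0 lower. DGAT2, which adds the last fatty acid to make triacylglycerol (ENSG00000062282, chromosome 11, 75759512 to 75801535), was at 2.03 (1.51 to 2.73) from 29 and 130 reads, and LPIN1, a phosphatidate phosphatase, at 1.33 (1.19 to 1.47). DGAT1, the other enzyme of that step, was at 0.43 (0.26 to 0.61), AGPAT2, an acyltransferase earlier in the pathway, at 0.88 and GPAM, which starts it, at 0.63, all under 2-fold.

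Fatty acid oxidation lists of A549 also lay above most random lists. The mitochondrial list had a median of 0.37 (percentile 99.1), with 3 of 21 genes at least 2-fold higher and 0 lower. SLC25A20, the acylcarnitine carrier, was at 1.28 (1.02 to 1.57), CPT1A, which makes acylcarnitines, at 1.13 (1.04 to 1.23) and ACADS, a short-chain dehydrogenase, at 1.08 (0.84 to 1.34). CPT2 at 0.97, ACADVL at 0.95 and HADHA at 0.27 were under 2-fold. The peroxisomal list had a median of 0.57 (percentile 99.8), with 3 of 14 genes higher and 0 lower and with PEX11A, a peroxisome division protein, at 2.12. Fatty acid synthesis and desaturation (0.33, percentile 96.3, 4 of 18 higher and 1 lower), lipolysis and lipophagy (0.35, percentile 93.8, 2 of 11 higher and 2 lower) and fatty acid activation and uptake (0.29, percentile 88.8, 5 of 13 higher and 2 lower) stayed within the range of random lists. With members of at least 100 reads the last 2 lists stood above it at 0.52 and 0.57, and so did the mean of fatty acid activation and uptake at 0.90. Single members were further apart, with CD36, a fatty acid receptor, at 4.63 (3.90 to 6.30), ACSL5, an acyl-CoA synthetase, at 4.86 (4.28 to 5.93) and SCD, the main desaturase, at 2.65, and on the lower side ELOVL2, a fatty acid elongase, at -2.60, SLC27A2, a fatty acid transporter, at -1.56 and MGLL, a monoacylglycerol lipase, at -1.35. FASN, fatty acid synthase, was at 0.70 and PNPLA2, the first lipase of droplets, at 0.82. Targets of the PPAR nuclear receptors had a median of 1.13 (percentile 100), with 8 of 15 higher and 1 lower.

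**Figure D2:**
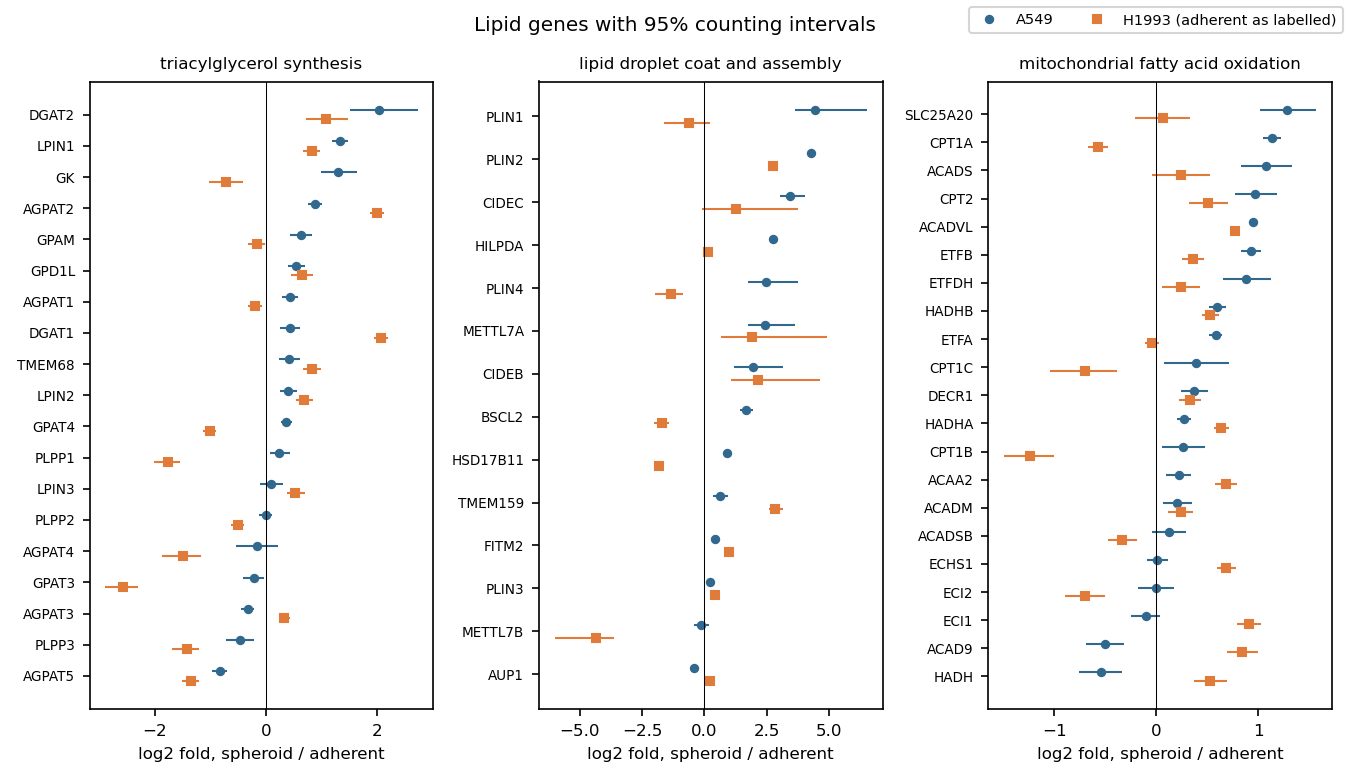
Log2 fold of spheroid over adherent (x axis) for genes of 3 lipid lists (y axis), with points for A549 and squares for H1993 as labelled, 1 library per culture, and lines for 95% counting intervals. Members with at least 10 reads in 1 library of each line are drawn, and PLIN2 stands at 4.28 in A549 and 2.77 in H1993.

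Genes induced by YAP and TEAD were lower in A549 spheroids. Of 26 measured targets, 15 were at least 2-fold lower and 3 higher, with a median of -1.13 (percentile 0.0). CYR61 (now CCN1, ENSG00000142871) had 1503 reads in adherent cells and 116 in spheroids, -3.74 (-4.04 to -3.49), CCDC80 was at -3.11, ANKRD1 at -2.40 (-2.90 to -2.02) and CTGF (now CCN2, ENSG00000118523) at -2.29 (-2.48 to -2.11). F3, tissue factor, went the other way at 2.15. YAP1 itself was at 0.19, its paralog WWTR1 at 0.13, TEAD1 at -0.87, TEAD2 at -0.17, TEAD3 at 0.37 and TEAD4 at -2.12 (-2.47 to -1.82). The Hippo pathway core list had a median of 0.06 (percentile 67.9), with 5 of 21 members lower and 1 higher. It holds YAP1, WWTR1 and the TEAD genes themselves beside the kinase cascade that restrains YAP. Its members LATS2, AMOTL1 and AMOTL2 are also in the list of YAP and TEAD targets. Actin cytoskeleton genes and targets of serum response factor had a median of -0.72 (percentile 0.01), with 6 of 23 at least 2-fold lower, 0 higher and all 23 below 0.

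Genes of the defence against reactive oxygen were less far apart in A549. Superoxide and peroxide detoxification had a median of 0.40 (percentile 98.1), with 3 of 20 higher and 0 lower, and GPX2, a glutathione peroxidase, stood at 1.32. SOD2 was at 0.67 and CAT, catalase, at 0.69. Targets of NRF2, the regulator of antioxidant genes, had a median of -0.34 (percentile 1.3), with 2 of 23 higher and 2 lower, and NQO1 was at 0.56. With the mean in place of the median neither list stood apart from random lists. Stem cell markers had a median of -0.16 (percentile 20.6), with 5 of 18 higher and 5 lower, and with members of at least 100 reads the median was 0.17, within the random range. CD44 was at 1.23 (1.19 to 1.27), ALDH1A1 at -0.58 and SOX2 at 0.17, the last from reads that all overlap a further gene model.

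Cholesterol synthesis and hypoxia genes were higher in A549 spheroids. All 23 cholesterol synthesis genes were above 0 and 17 at least 2-fold higher, with a median of 1.57 (percentile 100). MSMO1, a sterol oxidase, stood at 2.77 (2.66 to 2.88) and INSIG1, a regulator of sterol sensing, at 2.57 (2.46 to 2.69). Of 25 hypoxia genes 18 were at least 2-fold higher and 1 lower, with a median of 1.35 (percentile 100), led by NDRG1 at 4.57 and ANGPTL4 at 4.27. The unfolded protein response had a median of 0.73 (percentile 100), with 8 of 20 higher and 0 lower and with DNAJB9, a chaperone partner, at 2.72. Epithelial markers had a median of -0.48 (percentile 0.65), with 5 of 17 higher and 4 lower, and neither their mean of 0.045 nor their median of -0.21 with members of at least 100 reads was apart from random lists. Mesenchymal markers had a median of -0.10 (percentile 28.1). The gel-forming airway mucins MUC5AC and MUC5B stood at 5.76 and 4.64, with 170284 and 256797 reads in spheroids.

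**Figure D3:**
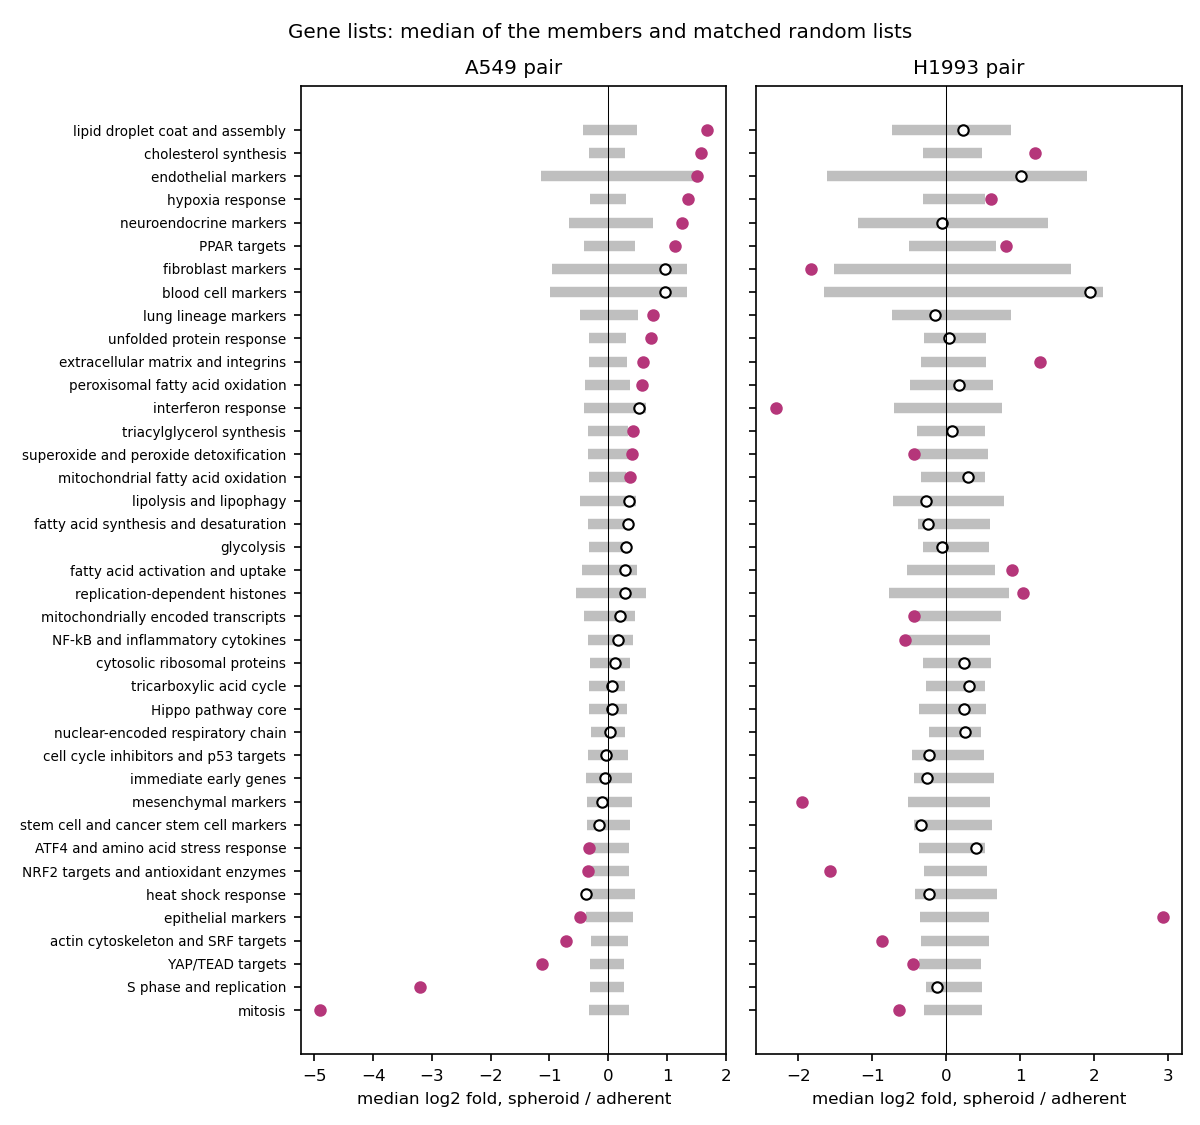
Median log2 fold of spheroid over adherent (x axis) of 39 gene lists (y axis) in the A549 pair and in the H1993 pair as labelled. Grey bars span 95% of the medians of 10000 matched random lists, filled points lie outside those bars and open points inside. Mitosis is lowest in A549 at -4.90 and epithelial markers highest in H1993 at 2.92.

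In the H1993 pair as labelled, epithelial genes were higher and mesenchymal genes lower in spheroids. Of 20 epithelial markers 16 were at least 2-fold higher and 0 lower, with a median of 2.92 (percentile 100). KRT19, a keratin of simple epithelia, stood at 5.596 (5.49 to 5.71), ESRP2, an epithelial splicing factor, at 5.17, CLDN7, a tight junction protein, at 4.71 and CLDN4 at 4.64. Of 20 mesenchymal markers 14 were lower and 1 higher, with a median of -1.95 (percentile 0.0), and the transcription factors TWIST1 and TWIST2 were at -4.25 and -4.18. In the same lists the library labelled H1993 adherent differed from A549 adherent cells by a median of -0.05 and 0.28, and H1993 spheroids differed from A549 spheroids by 2.36 and -1.56. GJA5, a connexin, was the highest abundant gene at 9.96 (from 1 read, 9.12 to 16.91). CGA, the alpha subunit of glycoprotein hormones, was at least 662-fold higher, FABP4, a fatty acid carrier, at least 342-fold and SLC14A1 at least 277-fold, each from 0 reads and against a floor of 3 reads in that library. PSG5, of a pregnancy glycoprotein family with closely similar copies, was at 8.57 (7.97 to 9.91). The lowest were DHRS3, a retinal reductase, at -7.95 (-10.93 to -7.10), CYP24A1, the vitamin D hydroxylase, at -7.79, INSL4 at -6.31, MMP24 at -6.29 and NRP2 at -5.91. By the same rule as in A549, 2593 genes were higher and 2752 lower in H1993 spheroids. CGA and FABP4 were not kept by the filter and are not among them. With no filter on low counts, 3489 genes were higher and 3072 lower. By the fold alone, 1.27% of genes simulated with no change passed 2-fold at a dispersion of 0.02 and 32.9% at 0.233.

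The lipid lists of the H1993 pair were spread to both sides. Triacylglycerol synthesis had a median of 0.08 (percentile 54.9), with 4 of 20 genes higher and 6 lower. DGAT1 was at 2.06 (1.95 to 2.19), AGPAT2 at 2.004 (1.88 to 2.13), DGAT2 at 1.08 (0.73 to 1.48), LPIN1 at 0.82, GPAM at -0.17 and GPAT3, another first-step acyltransferase, at -2.57 (-2.90 to -2.30). GPAT2 was at 3.41 from 13 and 140 reads. Lipid droplet genes had a median of 0.23 (percentile 66.0), with 4 of 15 higher and 4 lower. PLIN2 was at 2.77 (2.69 to 2.85), METTL7B at -4.35, PLIN1 at -0.63 (-1.63 to 0.21) and CIDEC at 1.25 (-0.11 to 3.75). Mitochondrial oxidation had a median of 0.29 (percentile 82.6), with 0 of 22 higher and 1 lower, CPT1B at -1.24. CPT1A was at -0.57, CPT2 at 0.51, ACADVL at 0.78 and HADHA at 0.64. Peroxisomal oxidation (0.17, percentile 65.1, 1 of 14 higher and 1 lower), lipolysis and lipophagy (-0.28, percentile 19.9, 1 of 11 higher and 2 lower) and fatty acid synthesis (-0.24, percentile 8.7, 5 of 18 higher and 5 lower) stayed within the random range. Fatty acid activation and uptake had a median of 0.89 (percentile 99.5), with 5 of 14 counted as higher and 1 as lower and with CD36 at 5.98 (5.25 to 8.12). FABP4, at least 342-fold higher, is 1 of the 14 but was not kept by the filter, so it is not among those counted as higher. PPAR targets had a median of 0.81 (percentile 99.2). FASN was at 1.83, SCD at 1.24 and PNPLA2 at 0.85. Between the 2 spheroid libraries, the median log2 difference, H1993 minus A549, was -1.64 for lipid droplet genes and -0.20 for triacylglycerol synthesis genes.

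Targets of NRF2 were lower in the H1993 pair, with 18 of 23 at least 2-fold lower, 0 higher and a median of -1.57 (percentile 0.0). ABCC2, an efflux pump, stood at -3.25, AKR1C3 and AKR1C2, aldo-keto reductases with closely similar copies, at -2.77 and -2.39, PGD, of the pentose phosphate pathway, at -2.61 and NQO1 at -1.95. The median of this list was -0.54 in the library labelled H1993 adherent relative to A549 adherent cells, and -1.89 in H1993 relative to A549 spheroids. Superoxide and peroxide detoxification had a median of -0.44 (percentile 2.5), with 4 of 21 higher and 5 lower. PRDX2, a peroxiredoxin, was at 4.78, GPX8 at -3.89, SOD2 at 0.61 and CAT at -0.45. With random lists of protein-coding genes, a prior count of 0.5 or the mean, this list no longer stood apart. YAP and TEAD targets had a median of -0.45 (percentile 0.96), with 9 of 26 lower and 6 higher. CTGF was at -5.19 (-5.92 to -4.72), CCDC80 at -4.70, CYR61 at -0.94, ANKRD1 at 4.55 (4.31 to 4.86) and F3 at 5.36. The Hippo core had a median of 0.24 (percentile 75.4), with LATS2, a Hippo kinase, at 2.27 and WWTR1 at -2.31 (-2.42 to -2.22). YAP1 was at -0.39, TEAD1 at 0.20, TEAD2 at -0.30, TEAD3 at 1.67 and TEAD4 at -0.85.

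Stem cell markers of the H1993 pair had a median of -0.35 (percentile 5.3), with 8 of 18 higher and 7 lower. With members of at least 100 reads the median turned to 1.10 and stood above random lists. ALDH1A1 was at -4.84 (-4.88 to -4.79), LIN28B at -4.42, SOX2 at -1.69 from 23 and 5 reads, CD44 at -0.58, EPCAM at 4.32 and KLF4 at 4.18. Cholesterol synthesis genes were higher, all 23 above 0 and 17 at least 2-fold, with a median of 1.20 (percentile 100). Hypoxia genes had a median of 0.60 (percentile 98.8), with 10 of 25 higher and 2 lower. Mitosis genes had a median of -0.64 (percentile 0.02), with 8 of 23 lower and MKI67 at -1.08 (-1.16 to -1.005). S phase genes had a median of -0.13 (percentile 12), with 3 of 24 higher and 3 lower. The unfolded protein response had a median of 0.04 (percentile 37.2), and actin and serum response factor genes one of -0.87 (percentile 0.0).

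Over both lines, 718 genes met the rule as higher in both spheroid libraries and 595 as lower in both. Independent lists of these sizes would share 321 and 285. With scaling by library size alone the counts were 607 and 697, so that the lower genes outnumbered the higher ones. Opposite calls were 278 genes higher in A549 and lower in H1993, where independent lists would share 340, and 191 the other way, against 268. The library labelled H1993 adherent lay close to A549 adherent cells, so the folds of the 2 lines have nearly the same baseline, and the counts for independent lists are not the values expected with no shared change. The 12 shared higher genes by the naming rule were SLC14A1, SPNS2, a sphingosine phosphate exporter (5.88 in A549 and, from 3 reads in the library labelled H1993 adherent, 7.29 with an interval of 6.51 to 10.35 in H1993), C2CD4A, SPTSSB, a subunit of the first sphingolipid enzyme (6.20 and 4.80), TCN1, CD36, MUC5AC, CAPN8, SDCBP2, TMEM45B, FGFBP1 and COL17A1, a hemidesmosome collagen (4.07 and 4.28). The 12 shared lower genes were ALPK2, MYOCD, a coactivator of serum response factor (-3.96 and -4.95), DPYSL5, BICC1, an RNA-binding protein (-3.80 and -4.46), DHRS3, SUSD2, RBM20, MAP2, ATP10A, CCL2, a chemokine (-4.65 and -3.61), CCDC74A and AOX1, aldehyde oxidase (-3.59 and -4.90). Across 15273 genes, folds in the 2 lines had a Pearson correlation of 0.28 and a Spearman correlation of 0.21. The shared lower targets of YAP and TEAD were CTGF, FOXF2, CCDC80, NUAK2, RBMS3 and AJUBA, the shared higher ones were F3 and IGFBP3, and 4 went opposite ways. Of the lipid lists, DGAT2, PLIN2, CIDEB, METTL7A, CD36, PNPLA3, ACSS2 and SCD were at least 2-fold higher in both lines, SLC27A2 (-1.56 and -3.17) and ELOVL2 (-2.60 and -5.52) lower in both, and FABP5, PLIN4, BSCL2, AADAC, ACOX2 and FADS2 went opposite ways.

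A test of culture with line as a block, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 15273 genes, called 0 genes higher and 0 lower, with a smallest adjusted p of 0.26. At an unadjusted p of 0.05 it had 1258 genes, 717 higher and 541 lower, and with library size alone 647 and 661. DESeq2 called 335 higher and 256 lower of 14680. Adjusted over the list alone, edgeR called 15 of 23 cholesterol synthesis genes, 9 of 22 genes of extracellular matrix and integrins, 8 of 25 hypoxia genes, 6 of 26 YAP and TEAD targets, 1 of 15 lipid droplet genes, and 0 of 20 triacylglycerol synthesis genes. Of the last list, 2 had an unadjusted p under 0.05 and DESeq2 called 0. The test had 1 residual degree of freedom, and on simulated counts at the fitted dispersion of 0.233 edgeR recovered 0 of 100 genes changed 4-fold and DESeq2 28. Both fits treat the library labelled H1993 adherent as its label says.

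**Figure D4:**
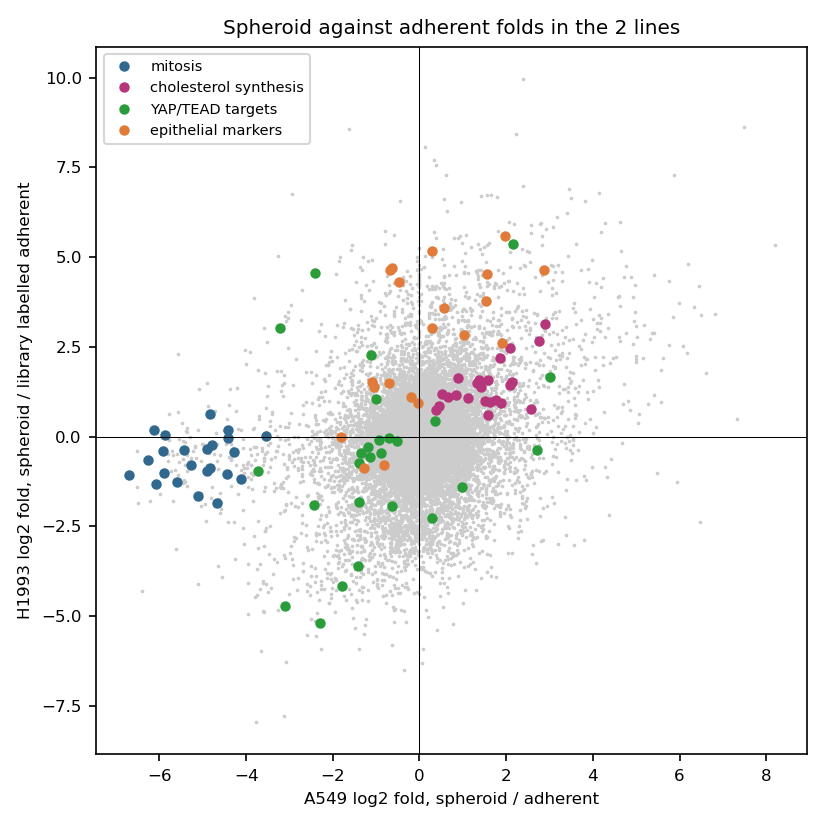
Log2 fold of spheroid over adherent in A549 (x axis) against H1993 as labelled (y axis), 1 point per gene over 15273 genes, with 4 lists coloured. All 23 cholesterol synthesis genes lie above 0 on both axes, and all 23 mitosis genes lie below 0 in A549.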

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

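The tests of expression shared with A549, of swapped libraries, of a small admixture, of scaling and of the line difference were chosen after the results were seen, and the position and intron tests before.

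The library labelled H1993 adherent lay closer to A549 adherent cells than to H1993 spheroids, and every H1993 fold uses it. A culture effect within 1 genome is argued against by the position excess of the H1993 pair, 2.95, against 1.14 in the A549 pair and a limit of 1.71. A swap of the 2 adherent libraries is argued against too, since A549 adherent cells correlated less well with H1993 spheroids than the library labelled H1993 adherent did (difference -0.032). Cells like the A549 libraries here are argued against as most of the library by 14 genes on in A549 and off in H1993 spheroids. Their median was 13.7% of the A549 adherent level, with the highest at 94.2%. A planned test of a genome like that of the A549 libraries here used the same limit of 1.71. The position excess of this library was 2.56 against A549 adherent cells, which by that rule argues against such a genome in most of the library. Against A549 spheroids it was 1.75. The excess divides by the SD after shuffling, which is smaller when 2 libraries are alike, so its size is not comparable between pairs. That SD was 0.055 between the adherent libraries and 0.094 in the A549 pair. The window SD, without that divisor, was still larger between the adherent libraries, 0.142, than in the A549 pair, 0.107. In the H1993 pair it was 0.382. The SD of the folds of single genes was 0.45 between the adherent libraries and 0.76 in the A549 pair. What stays open is a diverged A549 stock or another line, which was not tested, and a small share of H1993 cells in such cells, which cannot be told apart from culture effects on single genes: 43 genes on in H1993 spheroids and off in A549 had a median of 3.19% of the spheroid level and an interquartile range of 2.06 on the log2 scale.

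Lower proliferation genes in A549 spheroids were weighed against scaling and against a change in mature transcripts alone. With library size alone the mitosis median was -5.00. The TMM factors were 1.02 in A549 adherent cells and 0.94 in A549 spheroids. Leaving them out could move a fold only slightly, so this setting cannot decide about scaling. Summed intronic reads of the same genes fell by 3.44 on the log2 scale (from 2401 to 231 reads, interval -3.64 to -3.25), which argues against a change without intronic reads. A lower share of dividing cells in spheroid culture is a hypothesis that stays open, with 1 library per culture.

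Higher cholesterol synthesis genes in both spheroid libraries were weighed against a difference between lines in the H1993 pair. H1993 spheroids exceeded A549 adherent cells by a median of 1.15, which a line difference and a culture effect both need, and A549 spheroids by 0.16. For the H1993 pair the 2 cannot be told apart, because the library labelled H1993 adherent lies close to A549 adherent cells. The A549 pair holds no line difference. An effect of spheroid culture or of its medium may account for its values and stays open as a hypothesis, and the medium of each culture is not given in the sources used here.

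The following genes met the size rule in opposite directions in the 2 lines. The differences were not tested, and each is given as the H1993 minus the A549 log2 fold. Positive differences were 10.20 for PSG5 (from 13 and 3 reads in A549, where the interval of its fold was -4.63 to -0.32), 8.28 for ANXA8 and 6.34 for its close copy ANXA8L1, 6.96 for ANKRD1, 6.62 for EFEMP1, 6.47 for FBN2, 6.24 for AMOTL2 and 3.38 for LATS2. Negative differences were -6.67 for SIDT1, -6.60 for LUM, -5.88 for HLA-DMB, -5.74 for BMP6, -5.27 for IFI6, -4.65 for ATP8B4, -4.13 for GPX2, -3.68 for SLC2A3, -3.42 for AADAC, -3.38 for TP63 and -3.31 for ACOX2. The epithelial list stood apart in opposite directions with a difference of medians of 3.41, and superoxide and peroxide detoxification with -0.84. In A549 the epithelial list was not apart by its mean (0.045) or with members of at least 100 reads. By its mean the detoxification list was not apart in A549 (0.39) or in H1993 (-0.024). In H1993 it was also not apart with a prior count of 0.5 or among protein-coding random lists.

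Intronic reads lie outside the folds and list medians of the report. Summed over the cholesterol synthesis list their log2 fold was 1.47 in A549 and 1.56 in H1993, and over the hypoxia response 1.29 and 0.77. Of the 20 lists that stood apart in A549, the summed intronic reads lay on the same side beyond their counting interval in 14 and on the opposite side in 3, namely triacylglycerol synthesis (-0.12, interval -0.23 to -0.01, against an exonic median of 0.42), NRF2 targets (0.08 against -0.34) and neuroendocrine markers (-0.40 against 1.25). Of 17 lists in H1993 they lay on the same side in 12 and on the opposite side in 2, YAP and TEAD targets (0.58, interval 0.54 to 0.63, against -0.45) and superoxide and peroxide detoxification (0.35 against -0.44). In the other 3 lists of each line the interval held 0, in A549 mitochondrial (0.07 against 0.37) and peroxisomal oxidation (0.04 against 0.57) and endothelial markers (0.43 against 1.52), and in H1993 PPAR targets (0.04 against 0.81), mitochondrial transcripts (-0.40 against -0.43) and fibroblast markers (-0.61 against -1.82). A sum follows the genes with most intronic reads, which a median of genes does not.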

How the results depend on the processing

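Unique exon reads, the fit without mitochondrial genes and A549 libraries alone were chosen after seeing the data. No paired analysis by replicate was possible because there was 1 library per line and culture. The test over both lines has line as its block, and without either line's pair the test over both lines has no residual degrees of freedom, so no value was obtained. Of 58 values for size-rule counts 53 stayed within 1.5 times, and A549 libraries alone gave 2066 higher and 1633 lower genes. Requiring 100 reads in the line gave 1241 genes higher in A549, 379 higher and 353 lower in both lines, and 127 and 84 opposite. For both lines 11093 genes were then considered, against 15273 in the main setting. edgeR's 0 calls over both lines became 335 higher and 256 lower with DESeq2, and 127 and 46 with no filter on low counts, and stayed at 0 with other scalings, unique reads, no block and no mitochondrial genes, where 1209 to 1308 genes had an unadjusted p under 0.05. The cause was not tested.

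Of 541 list values 515 stayed on their side of the percentile limits and 0 that stood apart reversed. The 7 that newly stood apart were, in A549, fatty acid activation and uptake (mean 0.90; at least 100 reads 0.57), lipolysis and lipophagy (at least 100 reads 0.52) and glycolysis (mean 0.76), and in H1993 stem cell markers (at least 100 reads 1.10, from -0.35), blood cell markers (prior count 0.5, 2.85) and immediate early genes (mean -0.60). The 19 that no longer stood apart were, in A549 with the mean, NRF2 targets (-0.20), superoxide and peroxide detoxification (0.39), epithelial markers (0.045), the ATF4 response (-0.025), extracellular matrix (0.17) and endothelial markers (1.12). With at least 100 reads epithelial markers were at -0.21, and endothelial markers stood at 1.52 with a prior count of 0.5 and with protein-coding random lists. In H1993 with the mean they were superoxide and peroxide detoxification (-0.024), NF-kB (-0.30), fibroblast markers (-0.95) and histones (0.96). With at least 100 reads fibroblast markers were at -1.82 and histones at 0.89. With protein-coding random lists detoxification and mitochondrial transcripts were at -0.44 and -0.43. Detoxification with a prior count of 0.5 and mitochondrial transcripts with unique reads were both at -0.44. The cause was not tested. For named genes, 1920 of 2058 alternative values lay within the counting interval and 0 reversed. Depth limits genes with few reads, where intervals span several log2 units.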

Other observations

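Extracellular matrix and integrin genes were apart in both lines, with medians of 0.58 in A549 (percentile 100, 9 of 22 higher and 7 lower) and 1.26 in H1993 (12 higher, 6 lower). The A549 mean of 0.17 was not apart from the means of random lists. ITGB4, a hemidesmosome integrin, stood at 2.84 and 5.58, ITGA2 at 1.38 and 3.06, and the collagens COL4A1 at -2.53 and -4.42 and COL5A1 at -2.59 and -3.06. Interferon response genes had medians of 0.52 in A549 (percentile 93.8) and -2.31 in H1993 (percentile 0.0, 11 of 20 lower). NF-kB and inflammatory cytokine genes had medians of 0.17 and -0.56 (percentile 2.1), the latter not apart by its mean, and IL1B, a cytokine, stood at 3.40 and 6.22. The ATF4 response had medians of -0.33 (percentile 2.5, not apart by its mean) and 0.40 (percentile 92.9), with TRIB3, a stress pseudokinase, at 2.63 and 1.82. Glycolysis had medians of 0.30 (apart by its mean, 0.76) and -0.06, with HK2, a hexokinase, at 4.03 and 3.90. Cell cycle inhibitors and p53 targets had medians of -0.03 and -0.23, with CDKN1C at 3.53 and 3.58.

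Lung lineage markers had medians of 0.76 in A549 (percentile 99.6) and -0.16 in H1993. Among the lists not apart in either line were the nuclear-encoded respiratory chain (0.03 and 0.25), the tricarboxylic acid cycle (0.06 and 0.31), heat shock (-0.38 and -0.24), cytosolic ribosomal proteins (0.12 and 0.24), immediate early genes (-0.05 and -0.27) and blood cell markers (0.96 and 1.94). Mitochondrially encoded transcripts had medians of 0.19 in A549 and -0.43 in H1993 (percentile 2.4, not apart among protein-coding random lists or with unique reads), and replication-dependent histones 0.28 and 1.04 (percentile 99.1, not apart by its mean or with at least 100 reads). Neuroendocrine markers had medians of 1.25 (percentile 99.8) and -0.06, with CHGB, a granule protein, at 4.69 and 0.92. Fibroblast markers had medians of 0.97 and -1.82 (percentile 1.3, not apart by its mean or with at least 100 reads), and endothelial markers, with 3 and 4 measured members, 1.52 (percentile 97.53, not apart by its mean, with a prior count of 0.5 or among protein-coding random lists) and 1.01. MET, a receptor kinase gene known to be amplified in H1993 and chosen after its values were seen, stood at 286 CPM in A549 adherent cells, 246 CPM in A549 spheroids, 377 CPM in the library labelled H1993 adherent and 1701 CPM in H1993 spheroids.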
